A study of Homo sapiens with 4 samples.

How the data were processed

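The samples were LP-1 cells, a human multiple myeloma line, carrying a control short hairpin RNA or one against PSMD14. CUT&Tag was performed with a commercial kit, per the labels' protocols, and each of the 4 groups held 1 library. The groups come from the sample titles and the antibody field, which name H2AK119ub and H3K36me2. The protocol text in the labels names antibodies against PSMD14 or NSD2 in place of the histone marks, and a treatment field calls the control cells untreated while the treatment protocol gives them a control hairpin. The marks are therefore those of the titles, and this conflict could not be settled from the peak positions. In control, the list titled H2AK119ub had a peak near an end of 38.5% of HOX genes, which are classical Polycomb targets. Over all protein-coding genes this share was higher, 55.2%. In knockdown cells the order was the reverse, with 94.9% and 78.4%. The submitters' processing notes name fastp 0.19.6, Bowtie2, deepTools and the build GRCh38 (hg38). The peak caller, its threshold, any control library, the aligner settings and whether duplicates were removed are not given in the sources used here.

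The deposited files list peak positions, with no header, no counts and no scores. Each row holds a row number, a sequence name, a start, an end, a width and a strand. Start and end were equal and the width was 1 bp in each row used, so a row marks a single base, and the files do not say whether it is a summit or a centre. Covered length, peak width, peak strength and read depth could not be had from them, and a longer list can come from deeper sequencing as well as from more signal. The smallest distance between neighbouring peaks of a list was 295 bp.

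Row numbers showed that both H3K36me2 files, as read here, lack rows, and whether this holds for the files as deposited is not known. In the control file rows 37 to 33126 are absent (33090 rows, 15.0% of the numbering), which takes out chromosome 1 after position 509690, chromosome 10, and chromosome 11 up to 33968070, and 1 malformed row was left out as well. In the knockdown file rows 64 to 4668 are absent (4605 rows, 2.39%), between positions 875938 and 107708626 of chromosome 1. All comparisons of H3K36me2 with itself or with H2AK119ub used chromosomes 2 to 9, chromosome 11 from 33968070, chromosomes 12 to 22 and X. H2AK119ub alone used chromosomes 1 to 22 and X, except for distances to gene ends and for spacing, which used the smaller region. Peaks on other sequences were counted together and left out.

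Gene positions came from a RefSeq table of GRCh38.p14 with 19970 protein-coding genes on chromosomes 1 to 22 and X. It gives no strand and no transcripts, so promoters, planned as 2.5 kb either side of a start, were replaced by 2.5 kb either side of both annotated ends, called gene ends here. Exons, introns and untranslated regions were not used here. A gene counted as marked when a peak lay in this window. Peaks over a gene were counted from 2.5 kb before to 2.5 kb after it. Overlap by 1 bp, as planned, has no use for single positions, and peaks within 1 kb were taken as matched instead. Random placement used 100 circular shifts of at least 1 Mb along each chromosome, whose length was taken as the highest listed position.

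The rule for named genes was fixed before the data were examined, and was adapted to positions without scores. It took, per mark, the 10 genes with the most end peaks among genes marked only in knockdown cells and the 10 among genes marked only in control. It also took the 5 genes with the largest rise and the 5 with the largest fall in peaks over the gene, PSMD14, NSD2, up to 4 members of each gene list whose marking differed, with the most end peaks first, and the 5 longest runs gained and lost. Peaks of a library within 5 kb of each other were joined into a run, and single peaks were left out. A run was kept only if the other library had no peak from 1 kb before it to 1 kb after it. Ties were broken by symbol. The planned rule used peak values and covered bases. HOX clusters are given as counts over the cluster with 2.5 kb on either side, and were chosen after the list values were seen. The 24 gene lists, with 713 genes that were all found in the gene table, were written before the data were examined, and they include markers of plasma cells, B cells, T cells, myeloid cells, liver, neurons and epithelium. A list's number of changed genes was placed among 10000 random lists of the same size matched on gene length in 10 classes. This percentile describes these libraries and does not test the condition.

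No test between conditions was made, since each had 1 library. Shares carry 95% Clopper-Pearson intervals, and ratios of 2 counts carry the interval of the exact binomial share of their sum. Both cover counting error only, and neighbouring peaks are not independent. Relations across chromosomes were tested with 100000 two-sided permutations and Benjamini-Hochberg adjustment over 3 relations. Alternatives were merging of peaks within 1 kb, all sequences, windows of 1 and 5 kb, an empty window of 5 kb in the other library, shuffled placement and unmatched lists. Others were added after the data were seen. They were matching at 500 bp and 2.5 kb, random thinning of the longer list, whole genes, all rows present and row numbers. Lists matched on control marking, and windows and merging for the named genes, were added as well. Thinned shares of peaks found again are means of 20 draws, and thinned counts of gene ends come from a single draw.

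Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Recovery of changed genes was tested on the H2AK119ub control list and 19970 genes, of which 200 were given a peak and 200 others were stripped. Of the former 100% and of the latter 99.0% were recovered. Distances and gene counts equalled a direct search in 100% of cases. Of ratio intervals from separately simulated pairs of counts, 95.4% held the true ratio. Of random lists scored on the measured H2AK119ub gains, 2% lay above the 97.5th percentile.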

Results

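The data are 4 peak lists from CUT&Tag, an assay in which an antibody guides a transposase to its target in whole cells so that the DNA beside the target is cut out and sequenced. The cells were LP-1, a human multiple myeloma line, infected with lentivirus carrying a control short hairpin RNA or one against PSMD14. PSMD14 is a deubiquitinating subunit of the 19S cap of the proteasome. Each list is labelled for 1 of 2 histone marks. H2AK119ub, ubiquitin on a lysine near the end of histone H2A, is placed by Polycomb repressive complex 1. H3K36me2, dimethylation of a lysine of histone H3, is placed by NSD2 and related methyltransferases. There was 1 library per mark and condition, so no difference between the conditions was tested and none has a replicate check. Intervals are 95% exact intervals that cover counting error only, and they compare these libraries, not the conditions. Each peak is given as a single base position on GRCh38, with no width, height or read number, so the depth behind a peak is unknown. The H2AK119ub lists held 34853 peaks in control and 129567 in knockdown cells. The H3K36me2 lists ran to row 220753 in control and row 192572 in knockdown cells, but each list, as read here, lacked a block of rows, and this mark was compared over the 2613 Mb of 21 chromosomes that both lists covered.

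PSMD14 itself (chromosome 2, 161308425 to 161411717) carried no H2AK119ub peak within 2.5 kb of the gene or inside it in either library. Its H3K36me2 peaks were 1 in control, at 161308591, and 0 in knockdown cells. A histone mark peak does not measure expression, so the knockdown was not checked by these lists. NSD2 (chromosome 4, 1871393 to 1982192) had 2 H2AK119ub peaks in control and 7 in knockdown cells, a ratio of 3.5 with an interval of 0.666 to 34.5. It had no H3K36me2 peak in either library.

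The first comparison asked where H2AK119ub lay with and without the PSMD14 hairpin. The knockdown library listed far more peaks. On chromosomes 1 to 22 and X there were 34695 peaks in control and 129257 in knockdown cells, a ratio of 3.73 (3.68 to 3.77). The median distance between neighbouring peaks was 27162 bp in control and 6669.5 bp in knockdown cells, over the region compared for both marks. Of the control peaks, 90.1% (89.8 to 90.5) had a knockdown peak within 1 kb, where circularly shifted knockdown peaks gave 9.44%. Of the knockdown peaks, 25.5% (25.2 to 25.7) had a control peak within 1 kb. Every chromosome had a ratio above 3, from 3.10 (2.77 to 3.47) on chromosome 13 to 4.08 (3.81 to 4.37) on chromosome 22.

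The additional H2AK119ub peaks lay farther from genes' ends than the control peaks did. Within 500 bp of an end of a protein-coding gene, the ratio of knockdown to control peaks was 1.57 (1.52 to 1.63). It was 2.64 (2.49 to 2.79) from 500 to 1000 bp, 4.39 (4.18 to 4.62) from 2.5 to 5 kb, and 4.48 (4.40 to 4.55) beyond 5 kb. Peaks within 2.5 kb of a gene end made up 32.7% (32.1 to 33.2) of the control list and 19.4% (19.2 to 19.7) of the knockdown list, against 5.42% of the region itself. Inside protein-coding genes lay 52.3% of control and 52.9% of knockdown peaks, against 40.8% of the region.

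**Figure D1:**
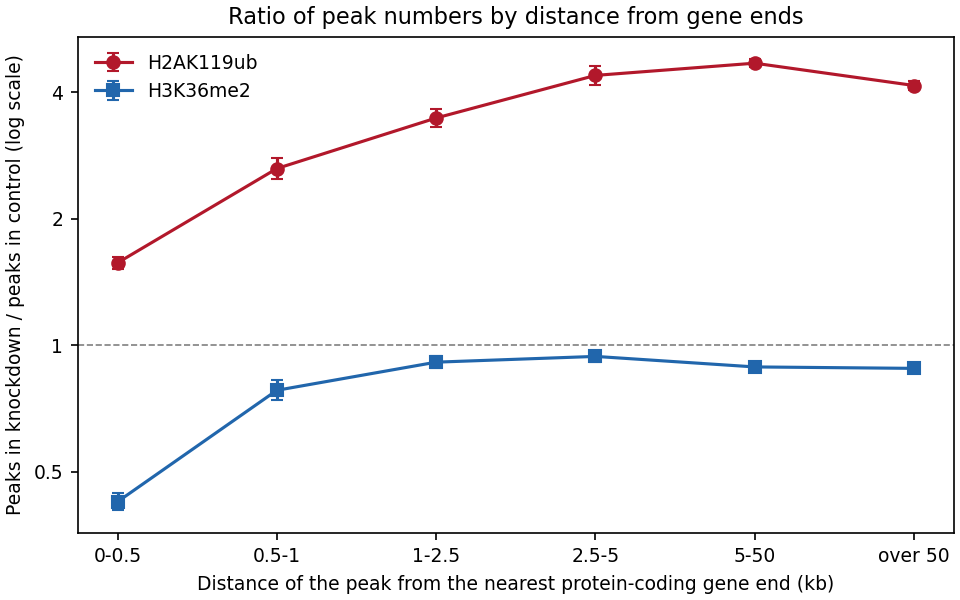
The number of knockdown peaks divided by the number of control peaks (vertical axis, log scale) is drawn against the distance of the peak from the nearest protein-coding gene end in kb, for H2AK119ub (red circles) and H3K36me2 (blue squares), with 95% counting intervals as bars. The H2AK119ub ratio runs from 1.57 within 500 bp to 4.15 beyond 50 kb with its highest value, 4.70, from 5 to 50 kb, and the H3K36me2 ratio runs from 0.424 within 500 bp to 0.881 beyond 50 kb.

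Of 19970 protein-coding genes, 11025 had an H2AK119ub peak within 2.5 kb of a gene end in control and 15654 in knockdown cells. There were 4829 genes with such a peak only in knockdown cells and 200 with one only in control. When the knockdown list was thinned to the length of the control list, in a single random draw, these counts were 1897 and 6303, so they depend on list length. Thinning drops peaks regardless of strength. Since 32.7% of control but 19.4% of knockdown peaks lay near gene ends, it favours control by construction. It does not stand for a shallower library. Over whole genes with 2.5 kb on either side, 13572 genes had more peaks in knockdown cells and 363 had fewer.

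The genes with the most H2AK119ub peaks at ends that carried none in control were RBP3 with 7, and DOCK6, GDF1 and SLC7A10 with 6 each. RBP3 (chromosome 10, 47348363 to 47357881) encodes a retinoid-binding protein of the retina. ARHGDIA, AVPR2, C14orf180, CARD10, CCDC187 and CDH4, the first by symbol of the genes tied there, had 5 each. With a window of 1 kb RBP3 had 3, SLC7A10 had 2, DOCK6 and GDF1 had 1, CDH4 had 0 and the other 5 had 2 or 3. Ends marked only in control carried few peaks. BIN3, C2orf74, CCDC102A, CDC40, H1-2, RUNX2 and WASF1 had 2 each, and ACSL5, ADD2 and ALG14, again the first of a tie by symbol, had 1 each. CDC40 and WASF1 are neighbours counted from the same 2 peaks. With a window of 1 kb BIN3, C2orf74, CCDC102A, CDC40 and RUNX2 had 1 and ACSL5 had 0. At BIN3 and CCDC102A the difference changed its direction with a window of 5 kb.

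By number of peaks over the gene, the largest H2AK119ub differences were at long genes. CAMTA1, which encodes a calmodulin-binding transcription activator, had 18 peaks in control and 131 in knockdown cells, a ratio of 7.28 (4.43 to 12.7). The neuronal splicing factor gene RBFOX3 had 17 and 127, a ratio of 7.47 (4.49 to 13.2). The cadherin genes CDH4 and CDH23 had 18 and 125, and 13 and 109. GSE1 had 40 and 141, a ratio of 3.53 (2.47 to 5.14), whose interval includes the ratio of all peaks. The largest differences in the other direction were of 2 peaks. ANO5, C1GALT1, CDC40, DBF4B and FBXW10B are the first by symbol of the genes tied at this difference, which also include H1-2 and WASF1, and each of these intervals includes 1.

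Runs of knockdown H2AK119ub peaks spaced by at most 5 kb, with no control peak inside or within 1 kb of the run, numbered 14835. Runs of control peaks without knockdown peaks numbered 33. These counts depend on list length, since the median distance between neighbouring peaks was 27162 bp in control and 6669.5 bp in knockdown cells. The longest knockdown run was 27282 bp with 10 peaks, inside EPHB2, which encodes an ephrin receptor (chromosome 1, 22735875 to 22763156). Others followed on chromosome 14 (104496097 to 104522603, nearest gene C14orf180), inside IQSEC1 on chromosome 3 (13188194 to 13214196), on chromosome 7 (1341131 to 1367034, nearest gene MICALL2) and on chromosome 11 (69521441 to 69546277). The last lay 94879 bp from CCND1, the cyclin D1 gene. Of the 5 longest runs found only in control, the longest was 6676 bp on chromosome 13 (17123403 to 17130078), 2043694 bp from the nearest protein-coding gene, TUBA3C. The others lay 1676018, 2924595 and 312221 bp from the nearest gene, and 1 lay at NSRP1. Regions of repeated sequence, where reads can be misplaced, were not filtered out.

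HOX genes, which specify position along the body axis and are classical Polycomb targets, stood out among the 24 gene lists. An H2AK119ub peak at a gene end was present at 15 of 39 HOX genes in control and at 37 in knockdown cells, or 38.5% and 94.9%. Over all protein-coding genes these shares were 55.2% and 78.4%, so in control HOX genes lay below the share of all genes. The 22 genes marked only in knockdown cells compare with a mean of 10.5 in the 10000 random lists of the same gene lengths. HOXB13 (chromosome 17, 48724763 to 48728750) had 0 end peaks in control and 4 in knockdown cells, HOXB3 and HOXB4 had 0 and 3, and HOXA11 had 0 and 2. With a window of 1 kb the knockdown peaks numbered 3 at HOXB4, 2 at HOXB13 and 0 at HOXB3 and HOXA11. Across the whole clusters the H2AK119ub peaks numbered 5 and 22 at HOXA, 7 and 32 at HOXB, 13 and 42 at HOXC, and 2 and 18 at HOXD. The ratio over all HOX genes, 4.18 (2.60 to 7.0), includes that of the whole list of peaks. Neighbouring HOX genes share windows, so these genes are not independent.

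**Figure D2:**
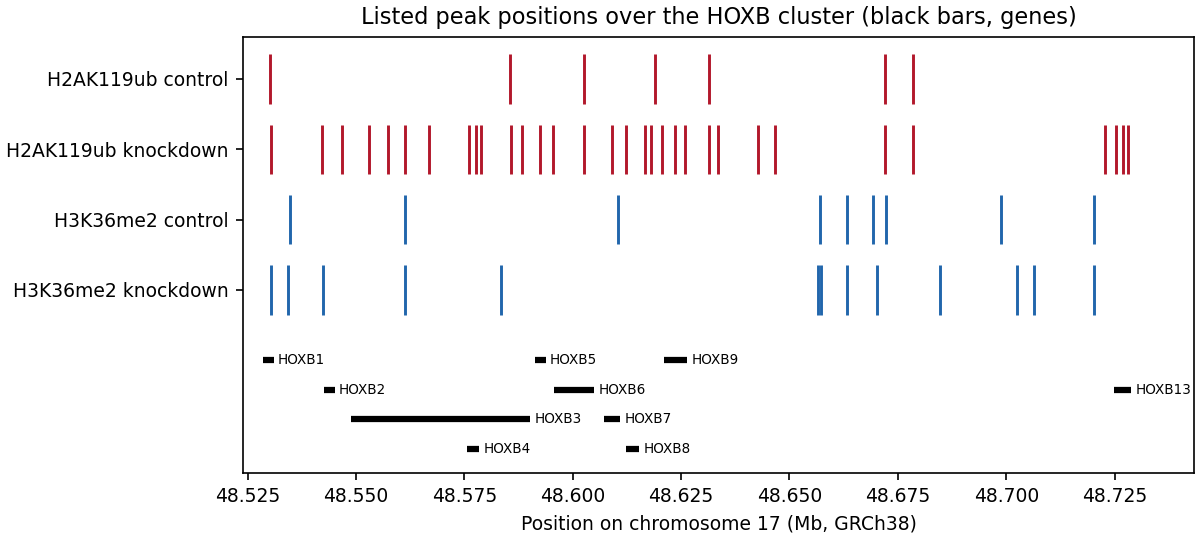
Listed peak positions of the 4 libraries are drawn as vertical marks along the HOXB cluster on chromosome 17 (48526026 to 48731250, horizontal axis in Mb), with genes as black bars. H2AK119ub peaks (red) number 7 in control and 32 in knockdown cells, a ratio of 4.57 (1.98 to 12.3), and H3K36me2 peaks (blue) number 9 and 13, a ratio of 1.44 (0.571 to 3.83).

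Each of the 24 lists had more members marked by H2AK119ub in knockdown cells than in control, and 4 lists besides HOX exceeded the limit set by random lists. Among 18 myeloid markers, 3 were marked in control and 14 in knockdown cells, with 0 and 5 end peaks at CSF3R, the G-CSF receptor gene, and 0 and 3 at MPO, which encodes myeloperoxidase. Among 22 T cell genes, 9 and 19 were marked. LAT, an adaptor of the T cell receptor, had 0 and 3 end peaks, and CD4 and CD7 had 0 and 2. Among 18 keratin and epithelial genes, 8 and 18 were marked, with 0 and 5 peaks at KRT7 and 0 and 4 at KRT17. Among 33 genes of cell adhesion and Wnt signalling, 19 and 32 were marked, and SFRP2, a secreted Wnt antagonist, had 0 and 3 end peaks. With a window of 1 kb the knockdown peaks numbered 2 at CSF3R and KRT7 and 1 at MPO, CD4, KRT17 and SFRP2. These 4 lists and HOX were the 5 of 24 whose number of genes marked only in knockdown cells lay above the 97.5th percentile of length-matched random lists, where 0.6 lists would by chance. Adhesion and Wnt passed narrowly, at 97.54, and fell to 97.28 with a window of 1 kb and to 97.38 without matching. Without matching 6 lists passed, namely HOX, myeloid, T cell, keratins, developmental transcription factors and clustered histone genes. Among genes without a control peak, matched on length, HOX, keratins, and adhesion and Wnt remained above it, and myeloid lay at 96.1 and T cell at 92.3.

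Other lists stayed below the limit when matched on length. Of 105 developmental transcription factor genes, 34 were marked in control and 69 in knockdown cells, at the 94.4th percentile and at the 98.2nd without matching. Matched on control marking as well, this list lay at percentile 5.1. DLX1, IRX4 and NKX2-5 had 0 and 3 end peaks. Subunits of Polycomb repressive complex 1 went from 16 to 22 of 25 marked and those of complex 2 from 6 to 9 of 12, with 0 and 2 end peaks at EZH2, the H3K27 methyltransferase. H2A deubiquitinases went from 8 to 12 of 15, and H3K36 writers and erasers from 11 to 15 of 18. Mature B cell genes went from 12 to 19 of 24, at percentile 84.9, with 0 and 4 end peaks at SPIB, or 0 and 2 with a window of 1 kb, and 0 and 3 at CD79A. Liver genes went from 6 to 12 of 20, at percentile 84.1, neuronal genes from 11 to 16 of 26, at percentile 36.7, and clustered histone genes from 11 to 27 of 47, at percentile 96.1 and, without matching, 98.0. Olfactory receptors went from 1 to 5 of 25.

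The remaining 9 lists had most of their genes marked already in control. The unfolded protein response list had 24 of 26 genes marked in control and 26 in knockdown cells, NF-kB pathway genes 23 and 27 of 27, and genes linked to NSD2 or the t(4;14) translocation 25 and 27 of 30. Cell cycle genes had 28 and 31 of 34, and plasma cell identity genes 20 and 21 of 26. Proteasome genes had 24 and 28 of 33, apoptosis genes 25 and 28 of 33, DNA repair genes 21 and 25 of 29, and ribosomal protein genes 31 and 44 of 50. Of the cell cycle list, the tumour suppressor gene CDKN2A had 0 and 3 end peaks. SLAMF7, in the plasma cell list, had 1 and 0, and this difference was 0 with a window of 1 kb and changed its direction with one of 5 kb. The ratio of peaks over whole genes was 1.89 (1.35 to 2.67) for the cell cycle, 2.0 (1.27 to 3.21) for the proteasome, 2.08 (1.41 to 3.11) for the unfolded protein response, 2.09 (1.37 to 3.24) for ribosomal proteins and 2.17 (1.49 to 3.20) for plasma cell identity. It was 2.33 (1.67 to 3.29) for apoptosis genes and 2.72 (2.06 to 3.64) for those linked to NSD2 or t(4;14). Each of these intervals lies below the ratio of the whole list of peaks, 3.73. Each includes the ratio of 2.22 of all peaks within 2.5 kb of gene ends, which counts gene ends alone and not whole genes. DNA repair genes, at 2.44 (1.62 to 3.75), and NF-kB pathway genes, at 3.32 (2.29 to 4.90), differ in this. Both of their intervals include 3.73, and that of the NF-kB pathway lies above 2.22. For T cell and myeloid genes the ratios were 4.91 (3.12 to 8.06) and 5.64 (2.94 to 11.9), and both intervals include 3.73.

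**Figure D3:**
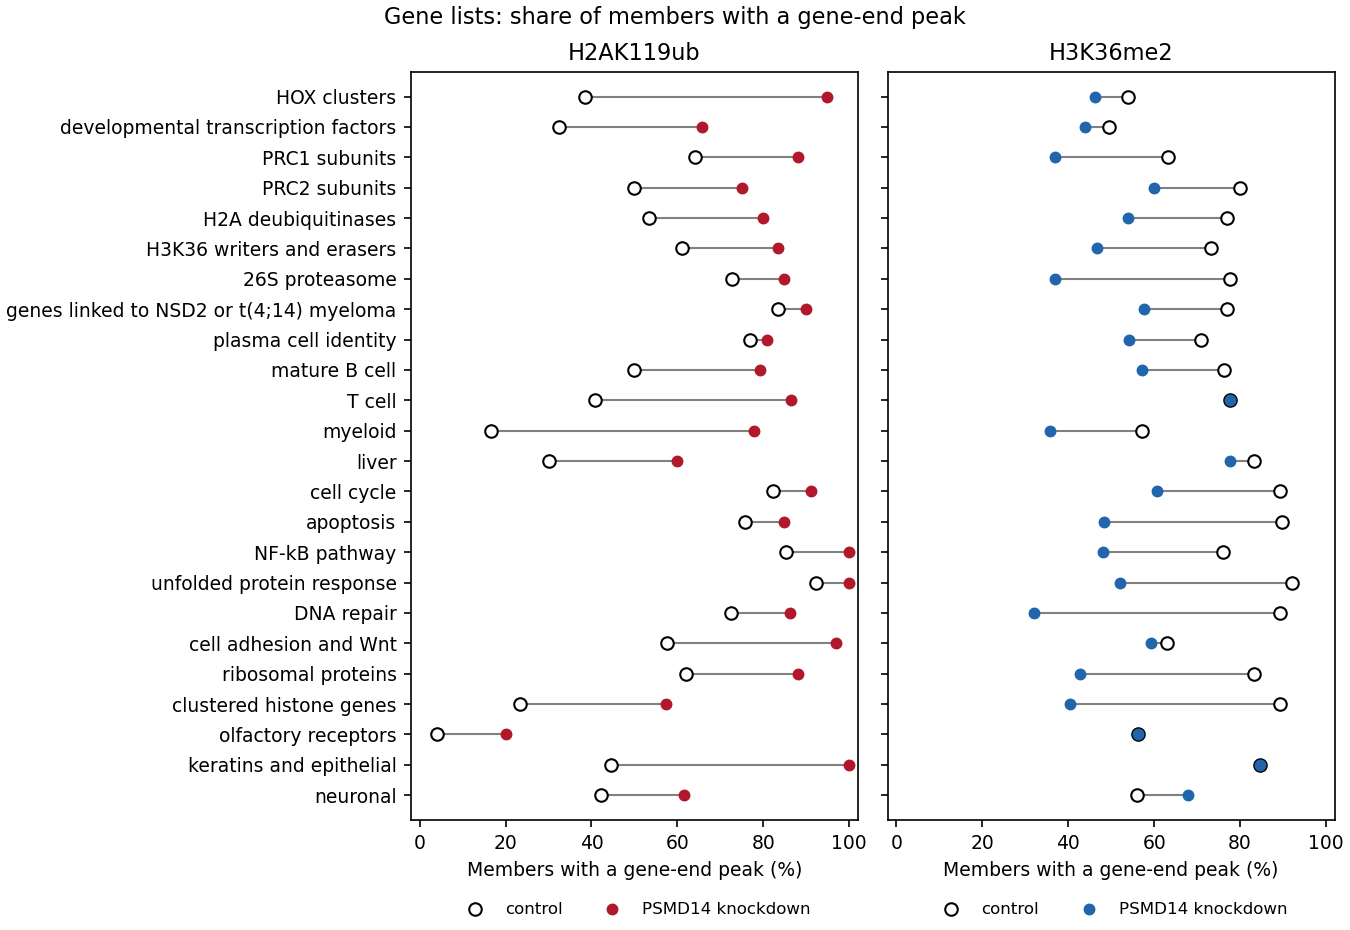
For each of the 24 gene lists, the percent of members with a peak within 2.5 kb of a gene end is drawn on the horizontal axis for control (open circles) and PSMD14 knockdown cells (filled circles), H2AK119ub at left and H3K36me2 at right. For H2AK119ub the HOX list runs from 38.5% to 94.9% and the plasma cell list from 76.9% to 80.8%, and for H3K36me2 the DNA repair list runs from 89.3% to 32.1% and the T cell list stays at 77.8%.

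The second comparison asked the same of H3K36me2. Here the knockdown library listed fewer peaks, and the shortfall was steepest beside gene ends. The compared region held 187173 peaks in control and 163010 in knockdown cells, a ratio of 0.871 (0.865 to 0.877). The highest row numbers of the lists gave 0.872. Counting all rows present, without regard to the absent blocks, gave 1.0, since more rows were absent from the control list as read here. Of the control peaks, 61.1% (60.8 to 61.3) had a knockdown peak within 1 kb, where shifted peaks gave 13.3%, and 69.6% (69.3 to 69.8) of the knockdown peaks had a control peak within that distance.

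Within 500 bp of a gene end, H3K36me2 peaks numbered 5906 in control and 2503 in knockdown cells, a ratio of 0.424 (0.404 to 0.444). Beyond 5 kb the ratio was 0.883 (0.877 to 0.890). Peaks within 2.5 kb of a gene end made up 8.43% of the control list and 6.81% of the knockdown list. Of 16814 genes in the region, 11993 had a peak at a gene end in control and 8559 in knockdown cells, with 4412 marked only in control and 978 only in knockdown cells. Over whole genes, 8622 had fewer peaks in knockdown cells and 2634 had more.

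PAFAH1B2 (chromosome 11, 117144287 to 117178173) had the most H3K36me2 end peaks among genes marked only in control, with 5 in control and 0 in knockdown cells. ATP13A1, CRELD1, DTX3L, PMPCB, PRELID3B, SLC27A5, TASP1, UBE4A and ZNF451 had 4 and 0. DTX3L and UBE4A encode ubiquitin ligases. In the other direction, BAHD1 and VSTM2L had 0 and 4, and ACKR3, ATP10B, FEZ1, HPGDS, MAPRE3, NUMBL, PIGU and PLEKHB2, the first by symbol of a tie, had 0 and 3. BAHD1 encodes a protein of silenced chromatin. With a window of 1 kb the control peaks numbered 2 at PAFAH1B2, 3 at PRELID3B and ZNF451 and 1 or 2 at the other 7, and the knockdown peaks numbered 3 at BAHD1, 1 at VSTM2L, 0 at HPGDS and 1 or 2 at the other 7.

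Over whole genes, the largest shortfalls were at DLG2, a synaptic scaffold gene, with 130 peaks in control and 101 in knockdown cells, a ratio of 0.777 (0.593 to 1.02), and at ADAMTSL1 with 56 and 28, a ratio of 0.5 (0.306 to 0.801). PARD3B had 74 and 46, CAST, the calpastatin gene, had 59 and 32, and ELMO1 had 52 and 25, a ratio of 0.481 (0.286 to 0.789), with the last 2 taken by symbol from a tie. The genes with the most additional peaks were TSHZ2 with 63 and 77, KALRN with 76 and 89, CSGALNACT1 with 46 and 58, TG, the thyroglobulin gene, with 33 and 44, and CLMP with 8 and 18. Each of the intervals of these last 5 ratios includes 1. Runs of control peaks without knockdown peaks numbered 5344 and runs of knockdown peaks without control peaks 2803. The longest of the former spanned 15038 bp with 5 peaks over FNTA, the farnesyltransferase alpha subunit gene (chromosome 8, 43041935 to 43056972), followed by runs over GRAMD1B and SCN3B, over MYH10, over TUBA1C, and on chromosome 2 (215669342 to 215681115) with FN1, the fibronectin gene, nearest. The longest of the latter spanned 13330 bp over DCAF4L1 on chromosome 4 (41969092 to 41982421).

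Gene lists with the largest excess of ends marked by H3K36me2 only in control held clustered histone, DNA repair, ribosomal protein and unfolded protein response genes. Clustered histone genes had 42 of 47 marked in control and 19 in knockdown cells, with 2 and 0 end peaks at H1-4 and H1-5, though 0 and 0 at H1-5 with a window of 1 kb. DNA repair genes had 25 and 9 of 28, with 2 and 0 at NBN, PRKDC and RNF168, or 1 and 0 at RNF168 with a window of 1 kb. RNF168 encodes a ubiquitin ligase for histone H2A. Ribosomal protein genes had 35 and 18 of 42, with 3 and 0 at RPL3 and RPL19. The unfolded protein response list had 23 and 13 of 25, with 3 and 0 at XBP1 and at the chaperone gene HYOU1, or 1 and 0 at XBP1 with a window of 1 kb. These 4 of 24 lists lay above the 97.5th percentile of length-matched random lists. The unfolded protein response list, at 97.8, fell to 97.1 without matching and to 88.8 among genes with a control peak. With a window of 1 kb all 4 lists passed, and so did proteasome and cell cycle genes, at 99.995 and 99.6. Histone genes lie in clusters and share windows. XBP1, also in the plasma cell list, encodes a transcription factor needed for antibody secretion. PRDM1, the plasma cell master regulator gene, had 2 and 0 end peaks, or 1 and 0 with a window of 1 kb. The plasma cell list as a whole had 17 and 13 of 24 marked. Only 4 of its genes were marked only in control, against a mean of 6.22 in length-matched random lists, at percentile 15.5.

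Among the remaining lists, proteasome genes had 21 and 10 of 27 marked by H3K36me2, apoptosis genes 26 and 14 of 29, cell cycle genes 25 and 17 of 28, and NF-kB pathway genes 19 and 12 of 25. PCNA, the replication clamp gene (chromosome 20, 5114953 to 5126622), had 3 end peaks in control and 0 in knockdown cells, or 1 and 0 with a window of 1 kb. Genes linked to NSD2 or t(4;14) had 20 and 15 of 26, with 2 and 0 at PAK1, or 0 and 0 with a window of 1 kb. Complex 1 subunits had 12 and 7 of 19, complex 2 subunits 8 and 6 of 10, and H2A deubiquitinases 10 and 7 of 13. H3K36 writers and erasers had 11 and 7 of 15, with 2 and 0 at SETD2 and NSD3. With a window of 1 kb SETD2 had 1 and 0. Of the lineage lists, T cell genes had 14 of 18 marked in both libraries with 0 marked only in control, where random lists averaged 4.88, at the 0.18th percentile. Neuronal genes had 14 and 17 of 25, with 1 marked only in control against an average of 6.64, at the 0.24th percentile. Over the whole neuronal genes the peaks were fewer in knockdown cells, 524 and 447, a ratio of 0.853 (0.750 to 0.970). Keratin and epithelial genes 11 and 11 of 13, liver genes 15 and 14 of 18, adhesion and Wnt genes 17 and 16 of 27, mature B cell genes 16 and 12 of 21, and myeloid genes 8 and 5 of 14. HOX genes had 21 and 18 of 39, developmental transcription factors 45 and 40 of 91, at the 2.11th percentile for ends marked only in control, and olfactory receptors 9 and 9 of 16. Among genes with a control peak, developmental transcription factors lay at percentile 30.1, T cell genes at 0.06 and neuronal genes at 0.81.

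The H3K36me2 ratio also differed between chromosomes. It was lowest on chromosome X, at 0.640 (0.601 to 0.681), and on chromosome 13, at 0.721 (0.684 to 0.759), and highest on chromosome 8, at 0.942 (0.922 to 0.963). Across the 21 chromosomes the ratio was higher where control peaks were denser. Pearson's r was 0.891 and Spearman's rho 0.842, each with a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give. The Benjamini-Hochberg adjusted value for rho was 3e-05 over 3 relations. Without chromosomes X and 8, the farthest from the median density, r was 0.829. With peaks beyond 5 kb of gene ends alone, r was 0.843 and rho 0.801 (permutation p of 1e-05 and 3e-05, adjusted 4.5e-05), and r was 0.786 without those chromosomes. For H2AK119ub the relation did not pass, with r of 0.290 (permutation p of 0.18) and rho of 0.223 (permutation p of 0.30, adjusted 0.30), and r was 0.406 without chromosomes 17 and 19. Chromosomes of the same libraries are not independent replicates.

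**Figure D4:**
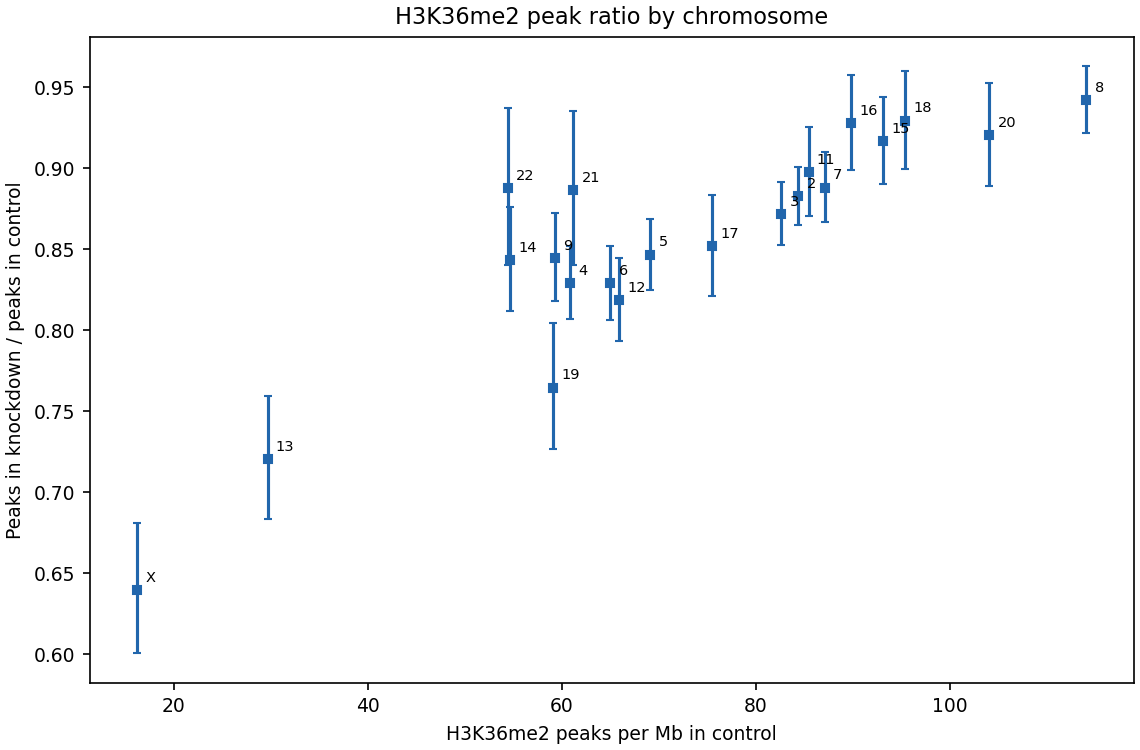
Each point is 1 chromosome, with H3K36me2 peaks per Mb in control on the horizontal axis and the ratio of knockdown to control peaks on the vertical axis, and bars are 95% counting intervals. Chromosome X has the lowest density, 16.2 peaks per Mb, and the lowest ratio, 0.640, and chromosome 8 has the highest density, 114.1, and the highest ratio, 0.942.

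The third comparison asked how the marks lay relative to each other. In control cells 56.5% (55.9 to 57.1) of H2AK119ub peaks had an H3K36me2 peak within 1 kb, 3.82 times the 14.8% of shifted peaks. In knockdown cells it was 44.9% (44.6 to 45.2), 3.44 times the 13% of shifted peaks. Of 79661 H2AK119ub peaks found only in knockdown cells, 37.3% (36.9 to 37.6) lay within 1 kb of an H3K36me2 control peak that was found again in knockdown cells, 4.07 times the shifted value. H3K36me2 peaks of control alone were within 1 kb of 11.2% (11 to 11.4), 1.92 times the shifted value, and those of knockdown alone were within 1 kb of 8.36% (8.17 to 8.55), 2.03 times. These ratios depend on the matching distance, and for the control-only peaks the ratio was 2.95 at 500 bp and 1.46 at 2.5 kb.

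By gene, H3K36me2 in control was more frequent at ends that carried H2AK119ub. An H3K36me2 end peak was present in control at 81.7% (80.9 to 82.5) of 9085 genes with H2AK119ub in both libraries, at 69.8% (68.3 to 71.2) of 4028 genes with H2AK119ub only in knockdown cells, and at 46.1% (44.5 to 47.8) of 3522 genes with none. Of the genes with an H3K36me2 end peak in control, the share without one in knockdown cells was 37% (35.9 to 38.1), 29.7% (28.1 to 31.5) and 46.1% (43.6 to 48.5) in these groups.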

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

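The tests in this part were chosen after the results were seen, except those on sites shared by both antibodies, and the differences between the marks were not tested, since each group held 1 library.

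The marks moved in opposite directions in the libraries. The ratio of knockdown to control peaks was 4.29 times higher for H2AK119ub than for H3K36me2 over the compared region, and 3.15 times higher for peaks within 2.5 kb of gene ends. In 20 of the 24 gene lists more members were marked by H2AK119ub and fewer by H3K36me2 in knockdown cells. The exceptions were T cell, olfactory, and keratin and epithelial genes, with equal numbers for H3K36me2, and neuronal genes, with more members marked but fewer peaks over the genes. All genes went this way, from 55.2% to 78.4% marked by H2AK119ub and from 71.3% to 50.9% by H3K36me2. Gene lists were not counted on thinned peaks. On sequences outside chromosomes 1 to 22 and X, which the comparisons leave out, H2AK119ub peaks numbered 158 in control and 310 in knockdown cells, a ratio of 1.96 (1.61 to 2.39).

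H2AK119ub peaks were 3.73 times as many in knockdown cells. The tables argue against copy number, since the lowest ratio of any chromosome was 3.10 (2.77 to 3.47), and against a control library that lost peaks of a common set at random. The share near gene ends was 18.2 percentage points higher in control peaks than in peaks found only in knockdown cells, with 32.7% and 14.5%. A deeper or more sensitive knockdown library may account for it, since 90.1% of control peaks had a knockdown peak within 1 kb. A spread of H2AK119ub in cells short of PSMD14 would keep the control peaks as well, and stays open and untested, as no read depth was known.

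The shortfall of H3K36me2 peaks at gene ends is not a uniform loss, since the ratio within 500 bp was 0.480 times that beyond 5 kb. A second explanation is signal at sites that both antibodies pick up, such as open chromatin, weaker in the knockdown library. It could apply at gene ends, where control H3K36me2 peaks not found again lay near a control H2AK119ub peak more often than those found again, by 17.3 percentage points (15.2 to 19.3). Distance to the end was not held fixed, so this cannot tell shared sites from closeness to the end. By gene, control H3K36me2 ends unmarked in knockdown cells were 37.4% (36.3 to 38.5) with control H2AK119ub and 35.7% (34.3 to 37.1) without. The share was highest, 46.1% (43.6 to 48.5), where neither library had H2AK119ub. Beyond 5 kb of gene ends the values went against the prediction of this explanation. There control H3K36me2 peaks near a control H2AK119ub peak were found again more often than others, by 21.2 percentage points (20.4 to 21.9). Without peak heights this match cannot exclude weaker signal at shared sites, since a weaker peak can still be listed. A loss of H3K36me2 at gene ends through PSMD14 stays open and untested.

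The H3K36me2 ratio was lower on chromosomes with few control peaks per Mb, with rho of 0.842 (permutation p of 1e-05, the smallest possible). A knockdown library of lower sensitivity, which drops peaks first where signal is weak, may give this pattern. A loss of the mark that differs between chromosomes would give it too, and was not tested.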

How the results depend on the processing

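Alternatives named as added were chosen after seeing the data, and in no case was the cause tested except where the construction shows it. Of 51 values that answer a comparison, 24 stayed within their interval or within 1.5 times, and 27 moved. Merging peaks within 1 kb gave an H2AK119ub ratio of 3.59 and 89.1% of control peaks found again, and 60.1% for H3K36me2. Added matching distances of 500 bp and 2.5 kb gave 82.7% and 93.8% for H2AK119ub and 55.6% and 70.2% for H3K36me2. Over shifted positions they gave 2.95 and 1.46 for H2AK119ub of knockdown alone near H3K36me2 of control alone, 6.13 and 2.14 for the marks in control, and 5.62 and 2.01 in knockdown cells, and shuffled positions gave 3.94 and 3.52 for the last 2. All rows present gave an H3K36me2 ratio of 1.0, since the control file as read here lacks more rows. Thinning the longer list, added, gave 25.5% of H2AK119ub control peaks found again. In a single draw it gave 1897 genes with H2AK119ub ends marked only in knockdown cells and 6303 only in control. For H3K36me2 a single draw gave 1482 only in knockdown cells. Thinning removes most knockdown H2AK119ub peaks by construction and regardless of strength, so its counts do not stand for a shallower library. A window of 1 kb gave 462 H2AK119ub ends only in control, and a window of 5 kb gave 632 H3K36me2 ends only in knockdown cells. Requiring the other library to be empty within 5 kb gave 132 H2AK119ub ends only in control, and 383 H3K36me2 ends only in knockdown cells and 2787 only in control. Whole genes, added, gave 486 H3K36me2 genes only in knockdown cells. With random lists matched on control marking, added, 3 lists exceeded the limit for H2AK119ub in place of 5. Without matching 6 did, as developmental transcription factors and clustered histone genes passed and adhesion and Wnt did not. For named genes under added windows and merging, the share of a gene's peaks that came from knockdown cells stayed within its 95% interval, which is wide at such counts, in 664 cases. It did not in 41 that had no difference with a window of 1 kb, and 3 reversed with a window of 5 kb, to differences of 2 at BIN3, 3 at CCDC102A and 2 at SLAMF7. The 664 cases include genes chosen for having no end peak in 1 library. A window of 1 kb or merging cannot add a peak there, so their share could not change while any peak was left. Such cases were fixed by the choice of genes and are no check. By size, of 236 differences in peak number 110 stayed within 1.5 times with a window of 1 kb and 126 shrank further, and 190 stayed with a window of 5 kb and 214 with merging. A stricter threshold, the strongest peaks, covered length, overlap by 50% and the 5' end alone were not run, as the files give no peak value, width or strand. No paired analysis was possible because each group holds 1 library. Depth is unknown and limits each ratio of peak numbers.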

Other observations

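The test on HOX and developmental genes was written before its own result was seen, but its matching on control marking was added after other results of these libraries, and the values on shared bases were also chosen after the data were seen.

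The share of genes with an H2AK119ub end peak in control was 55.2% over all protein-coding genes. It differed widely between lists, and no theme was tested. The highest shares were 92.3% in the unfolded protein response, 85.2% in the NF-kB pathway, 83.3% in the list linked to NSD2 or t(4;14) and 82.4% in the cell cycle list. Ribosomal protein genes were at 62%. Below the share of all genes lay, among others, HOX genes at 38.5%, developmental transcription factors at 32.4% and clustered histone genes at 23.4%. The lowest were myeloid genes at 16.7% and olfactory receptors at 4%. HOX genes are classical Polycomb targets, so their low share in control leaves open the conflict over the antibodies in the labels. XBP1 carried H2AK119ub peaks at both ends in control, at 28792330 and 28800534 on chromosome 22, and in knockdown cells, at 28792152 and 28800532. Its H3K36me2 end peaks in control lay at 28792529, 28800324 and 28802925. PCNA had H2AK119ub end peaks in control at 5113283, 5126598 and 5127660 on chromosome 20 and H3K36me2 end peaks at 5113164, 5126699 and 5127795.

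One hypothesis was that Polycomb targets take up a larger part of the new H2AK119ub peaks than other genes of the same length without a control peak. Of 24 such HOX genes, 22 were newly marked, against a mean of 14.5 in matched random lists. Developmental transcription factors argue against it as a rule for Polycomb targets. Of 71 without a control peak, 35 were newly marked against a mean of 41.7, at percentile 5.1 of matched lists. HOX genes share windows, and the high share was not particular to them, since 10 of 10 keratin and epithelial genes and 13 of 14 adhesion and Wnt genes without a control peak were newly marked as well.

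A small share of the peaks of separate libraries was listed at exactly the same base, more than at nearby offsets. For H3K36me2, 10969 positions were identical in control and knockdown cells, 6.73% (6.61 to 6.85) of the knockdown peaks of the compared region, against a mean of 798.4 per base at offsets of 1 to 10 bp. Shares of the shorter list were lower for the other pairs. Between H2AK119ub libraries the count was 558, or 1.95% (1.79 to 2.12), against 106.1. Between different marks in knockdown cells it was 779, or 0.730% (0.679 to 0.782), against a mean of 180.0, and in control 132, or 0.462% (0.386 to 0.547), against 41.6. No explanation was tested.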
